A study of Lactiplantibacillus plantarum with 6 samples.

How the data were processed

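RNA from 6 samples of Lactiplantibacillus plantarum WCFS1 was sequenced, 3 controls and 3 treated with 3OC12. Per the labels' protocols, cells were opened with lysozyme, RNA was isolated with RNAzol RT, and libraries followed standard Illumina protocols. The concentration of 3OC12 and its solvent are not given in the sources used here. The deposited file holds raw counts of reads per annotated feature in each library, which the authors made without normalization, as its whole numbers and unequal totals show. Trimmomatic 0.33, Bowtie2 and DESeq2 1.8.1 are named in the submitters' processing notes, without role or order. The counting program, the strand setting and the genome build are not given in the sources used here. Product names, locus tags and positions come from the deposited table, which holds a chromosome and 3 plasmids. The table gives no strand, so reads of overlapping or antisense genes cannot be told apart. The reference table of gene symbols was of another strain, matched none of the locus tags and was not used.

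The table names 3151 features, of which 34 had 0 counts in every library. A further 7 summary lines were left out of library sizes and tests. Reads that aligned outside features made up 5.86% ± 0.25 of control and 5.31% ± 0.42 of treated reads in the table (SD, n = 3), reads not aligned 2.46% and 2.35%, and reads over more than 1 feature 1.13% and 1.16%. Reads of low alignment quality made up 0.306% and 0.562%. The table lists 0 reads as not uniquely aligned in every library, so how reads from repeated genes were assigned is not known, and values of transposases and prophage genes are uncertain. A summary total in the deposited table left out the plasmid genes in 5 of the 6 libraries, all but treated library 1, and was not used. Counts in genes ranged from 2517743 to 4709820 per library. PCR reads without molecular identifiers are not independent molecules, so depth describes counting error only. No pair of libraries was alike within sampling noise, the lowest chi-square per degree of freedom being 3.32.

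Counts were analysed in R 4.3.3 with edgeR 4.0.16, using TMM normalization, filterByExpr with a minimum count of 10, and the quasi-likelihood F-test on group alone, which left 2932 features (2909 protein-coding, 19 tRNA, 3 small RNA and 1 rRNA). P-values were adjusted by Benjamini and Hochberg with a threshold of 0.05, and a gene rose or fell if it passed. The biological coefficient of variation was 8%. Standard errors are the absolute log2 fold change over the square root of F. CPM are TMM-normalized. In all, 32 gene lists were fixed before the data were examined, by symbol, product name and locus tag. The table has no symbols, so only product names and locus tags were matched. Members given by symbol alone are therefore missing, and a list can hold a mere part of its pathway. Of these 3 were composition checks and 27 had at least 3 tested members. Not tested were an envelope stress list with 0 members and a quorum sensing list with 1, luxS. RNA classes were taken from feature types instead of list patterns, which also matched RNA-modifying enzymes. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry, with adjustment over the 27 lists. The preset called 9 lists (5 down, 4 up), the estimated correlation called 0, and fry, which asks whether members move on balance in a direction and compares them with no other genes, called 4. Those 4 were heat shock, cysteine and methionine, ATP synthase and phosphotransferase genes. Runs were sought among neighbouring tested genes with strand ignored and compared with 10000 shuffles. Shares of counts were compared with exact two-sided permutation tests.

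Genes were named by a rule set before the data were examined. It took the 10 largest rises and 10 largest falls among passing genes whose groups did not overlap, up to 3 members per list by smallest p, the ends and largest member of the 5 longest runs, and lp_0775 with 2 neighbours on each side. Genes outside it are said to be so. Titles share the numbers 1, 2 and 3 between groups. Deviations from the group means correlated at 0.166, 0.220 and 0.135 for the 3 same-numbered pairs, and at -0.212 to 0.058 for pairs of unlike number. Deviations within a group cancel, so these values are not independent. The numbers were taken as a likely pairing of the samples, from the data alone. The main fit on group alone was kept as planned, and a replicate block was fitted as an alternative.

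On simulated counts for 2923 genes in this comparison, with 50 genes changed at each fold size, the test recovered 66% at 1.3-fold, 70% at 1.5-fold, 98% at 2-fold and 100% at 3-fold. The changed genes were drawn from those above a minimum mean count, so recovery of weakly expressed genes was not measured. The test made 185 calls, 18 of them on unchanged genes, and 0 calls when no gene was changed. In this single simulation the share of false calls was above the 0.05 that the threshold aims at. Alternatives were DESeq2 1.42.0, limma-voom, 3 other scalings, 2 other filters, the replicate block, counts without RNA genes, and each library left out in turn. Added after seeing the data were a correction for gene length by loess on each library, the same with the replicate block, thinning of all libraries to the smallest, treated library 2 alone against the controls, the cold shock list without matches to "related", shares of counts with each library left out, and small stable RNA shares within pairs. GC content was not analysed here. The neighbourhood of lp_0775 was in the rule from an unchecked recollection of its promoter.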

Results

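The transcriptome of Lactiplantibacillus plantarum WCFS1, a Gram-positive lactic acid bacterium, was measured by RNA sequencing with and without 3OC12. This molecule, an acyl homoserine lactone, is a signal by which Gram-negative bacteria such as Pseudomonas aeruginosa sense their own density. Cells received 3OC12 at an OD600 of 0.5 and were harvested after 1 doubling. The series comprised 6 libraries, 3 from control cells and 3 from treated cells. The control libraries held 3758142, 4235856 and 4709820 counts in genes, and the treated libraries held 2584965, 4526081 and 2517743. Treated libraries 1 and 3 were thus the shallowest. Nothing in the labels says that the replicates were separate cultures, so p-values measure the spread among these samples, which may be technical.

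The comparison of treated with control cells asked which genes differ in RNA level after 3OC12. Promoters were not analysed. Single genes for a manganese transporter (lp_2992) and a compatible solute transporter (lp_3324) were among the largest rises. By camera at a preset correlation 9 gene lists were called, 5 down and 4 up, among them sugar phosphotransferase, polysaccharide, prophage and ATP synthase genes (down) and cysteine and methionine metabolism (up). With an estimated correlation 0 lists were called. List calls at the preset are therefore weak evidence. At the preset, 2 to 6 lists were also called in every other split of the 6 libraries into 3 and 3. Those splits keep part of the treatment difference, so they cannot give the rate of false list calls. Of 2932 tested genes, 362 changed (12.3%), of which 169 rose and 193 fell in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The median absolute log2 fold change of the changed genes was 0.39, and 9 genes changed at least 2-fold, 1 up and 8 down. In 360 of the 362 changed genes the treated and control libraries did not overlap, which passing a test on the same values makes likely, so it adds no evidence. At an unadjusted p under 0.05 there were 849 genes. With a block for the replicate number in the fit, 540 genes passed the adjusted threshold (242 up, 298 down). Over all tested genes the groups did not overlap in 32.5%, where chance gives 10%. The balance of directions depended on scaling, with 228 rises and 148 falls after upper-quartile scaling and 250 rises and 144 falls with library totals alone. The count fell to 120 without control replicate 3, to 145 without treated replicate 1 and to 232 without treated replicate 3, and the count of 2-fold changes was 14 without control replicate 2, 23 without treated replicate 2 and 16 without treated replicate 3.

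The largest rise was in lp_2993, which encodes a universal stress protein of the UspA family, a group of nucleotide-binding proteins made under many stresses. Its level went from 5.42 ± 1.02 to 14.4 ± 3.73 CPM (SD, n = 3 per group), a log2 fold change of 1.37 ± 0.26 (SE) with an adjusted p of 0.00732 in edgeR. The neighbouring gene lp_2992, annotated as a manganese transport protein, rose from 21.6 ± 1.52 to 42.2 ± 3.08 CPM (log2 fold change 0.96 ± 0.12, adjusted p = 0.00117). The pair lies at positions 2662014 to 2664037 of the chromosome. The best expressed gene among the 10 largest rises was lp_3324, a glycine betaine, carnitine and choline transporter, the kind of protein that takes up compatible solutes. It rose from 624.9 ± 32.5 to 1049.9 ± 56.7 CPM, with a log2 fold change of 0.75 ± 0.07 and an adjusted p of 0.000228. Further rises were found for lp_1750, an iron ABC transporter ATPase (0.99 on the log2 scale), lp_0892, a MarR family regulator (0.92), and lp_0252, a hypothetical protein (0.84). The remaining 4 were lp_0353, an extracellular zinc metalloproteinase (0.80), lp_2314, a glutamine and histidine ABC transporter permease (0.62), lp_0259, a nicotinamide mononucleotide transporter (0.59), and lp_0800, a cell surface protein with an LPXTG cell wall anchor (0.58). After thinning, lp_1750 and lp_0353 lost their call. Of these 10 genes, 5 passed in all 6 fits that left out 1 library. The call was lost for 5 without control replicate 3, for 4 without treated replicate 1, for 4 without treated replicate 3, for 3 without control replicate 1 and for 1 each without control replicate 2 and treated replicate 2.

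The best expressed gene among the 10 largest falls was lp_2987, a hypothetical protein that fell from 6967.7 ± 832.1 to 3471.9 ± 415.6 CPM (a fold of 0.498, adjusted p = 0.000243 in edgeR). The Na+/H+ antiporter gene lp_2827, whose product exchanges sodium for protons across the membrane, fell from 158.6 ± 3.68 to 79.0 ± 5.98 CPM (-1.01 ± 0.08, adjusted p = 0.000113). Galactokinase, lp_3482, the enzyme that phosphorylates galactose after uptake, fell from 70.8 ± 6.87 to 33.5 ± 6.15 CPM (-1.05 ± 0.14, adjusted p = 0.00127). Of an ABC transporter, the permease gene lp_0161 fell by 1.05 and the ATP-binding gene lp_0160 fell by 0.94 on the log2 scale. The hypothetical protein gene lp_1123 fell by 0.97. The other 4 falls were in genes under 13 CPM in control cells. They were a transposase fragment, lp_1213 (-1.50), a glycosyltransferase, lp_1215 (-1.30), and the prophage genes lp_2406 (-1.30) and lp_0642 (-1.13). Transposase and prophage genes can have near-identical copies among which reads are split, so their values are uncertain. After thinning, lp_1215 and lp_0642 lost their call. Of the 10 genes, 7 passed in all 6 fits that left out 1 library, with 3 calls lost without control replicate 3, 2 without treated replicate 1, and 1 each without control replicate 1, control replicate 2 and treated replicate 2.

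**Figure D1:**
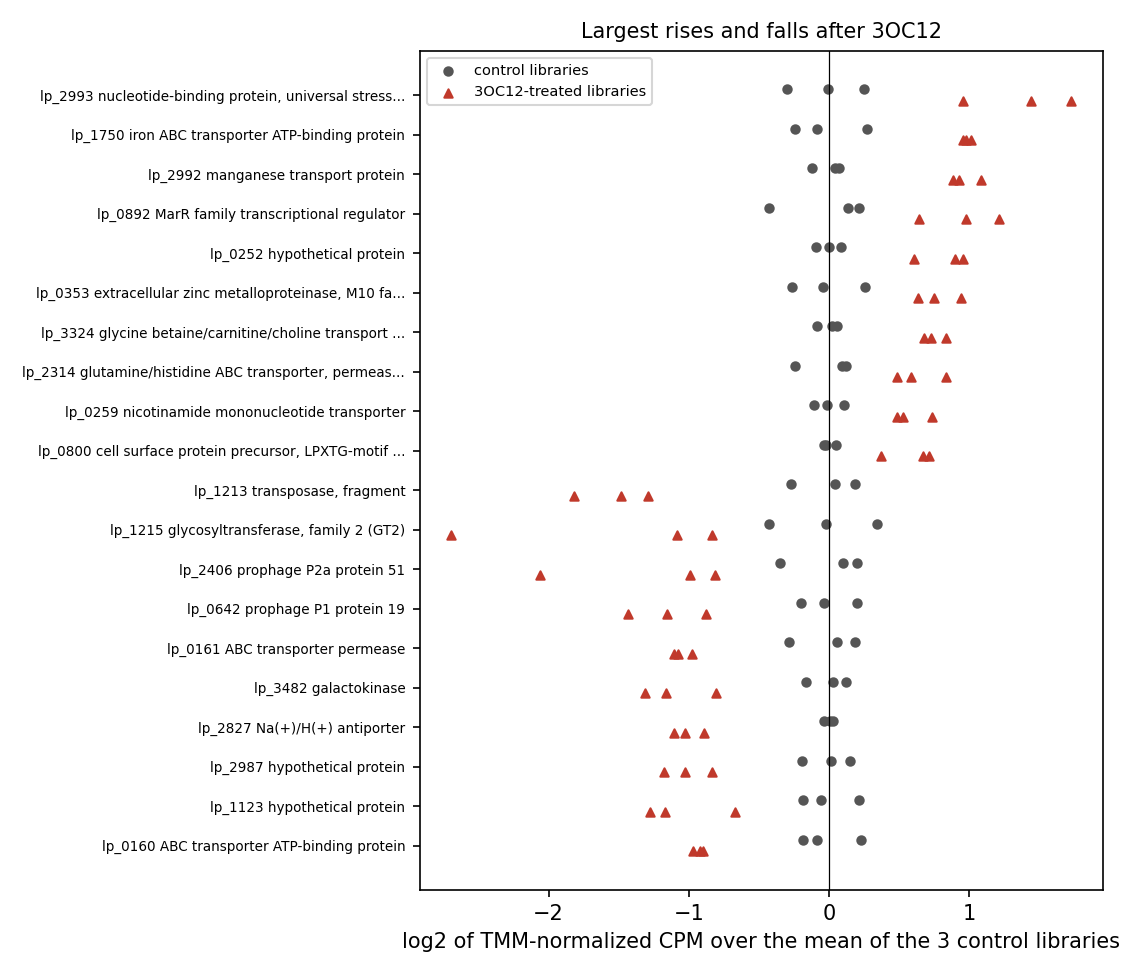
The plot of single libraries for the 10 largest rises and 10 largest falls. The horizontal axis is the log2 ratio of TMM-normalized CPM to the mean of the 3 control libraries, circles are control and triangles treated libraries, and in each gene the 3 treated values lie on the same side of all 3 control values.

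Genes of capsular and exopolysaccharide synthesis were lower in treated cells. Of 35 tested members, 34 had a negative fold change, 8 fell and 0 rose, and adjusted over the list alone 17 fell. The median log2 fold change was -0.31 (camera, adjusted p = 2.85e-06, and adjusted p = 0.49 with an estimated correlation). The member with the smallest p was lp_1219, UDP-galactopyranose mutase, which makes a galactofuranose donor for surface glycans, and it fell from 80.0 ± 4.46 to 47.2 ± 6.32 CPM (-0.77 ± 0.11, adjusted p = 0.00222 in edgeR). The polysaccharide biosynthesis gene lp_1220 fell by 0.58 and the O-acetyltransferase gene lp_1226 fell by 0.44 on the log2 scale. Of these 3 genes, lp_1226 lost its call with DESeq2, without control replicate 1 or 3 and without each of the treated replicates.

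Prophage genes had a median log2 fold change of -0.31 over 123 tested members, with 108 negative values, 8 falls and 1 rise. The falls were no more frequent than among all 2932 tested genes, of which 193 fell and 169 rose. Adjusted over the list alone, 2 fell and 0 rose. Camera gave an adjusted p of 3e-05, and adjusted p = 0.64 with an estimated correlation. Besides lp_0642 and lp_2406, the member named by rule was lp_2453, an ATPase of prophage P2a, which fell from 647.3 ± 32.9 to 519.6 ± 29.7 CPM (-0.32 ± 0.07, adjusted p = 0.0143 in edgeR). Without treated replicate 2 the median was -0.21 (adjusted p = 0.0376), and with treated replicate 2 as the lone treated library it was -0.60.

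All 8 genes of the ATP synthase, the proton-translocating enzyme of the membrane, had a negative fold change. In the test over all genes 4 fell, and adjusted over the list alone 8 fell. The median log2 fold change was -0.26 (camera, adjusted p = 0.000103, and adjusted p = 0.49 with an estimated correlation). The A subunit gene lp_2370 fell from 4906.3 ± 143.7 to 3895 ± 107.8 CPM (-0.33 ± 0.07, adjusted p = 0.00821 in edgeR), the C subunit gene lp_2369 fell by 0.32 and the B subunit gene lp_2368 fell by 0.29. The call of lp_2369 ended with the length correction (adjusted p = 0.158), and lp_2368 lost its call without each of the treated replicates.

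Heat shock and protease genes were lower as a group. Of 17 members, 8 fell and 0 rose, and adjusted over the list alone 9 fell and 1 rose. The median log2 fold change was -0.23 (camera, adjusted p = 0.00058, and adjusted p = 0.37 with an estimated correlation). The small heat shock protein genes lp_3352 and lp_2668 fell by 0.45 and 0.39 on the log2 scale, from 1320.1 ± 95.7 to 966.5 ± 97.1 CPM and from 1136.2 ± 124.6 to 864.6 ± 26.8 CPM. The gene of ClpC, an ATPase that feeds proteins to the Clp protease, fell by 0.30 (lp_1019, adjusted p = 0.0143 in edgeR). GroEL (lp_0728) had a log2 fold change of -0.05 with an adjusted p of 0.707 and is given here although the rule for named genes did not select it. The cold shock list as fixed held 18 genes, of which 15 matched only through the word "related" in the product name, and with 2 rises and 2 falls it was not called (median -0.17, adjusted p = 0.407). Its 3 true cold shock genes, taken alone after this was seen, held 2 falls and a median of -0.46. Camera at the preset correlation called these 3 down (adjusted p = 0.00832), and an estimated correlation was not tried for them. Among them lp_1160, encoding the cold shock protein CspP, fell from 3619.3 ± 172.5 to 2634.9 ± 436 CPM (-0.46 ± 0.10). The calls of lp_1160 and lp_2668 were lost without control replicate 3, and that of lp_1160 also without treated replicate 1. The list as fixed passed without treated replicate 2 (adjusted p = 0.0412), and without treated replicate 1 its median was -0.10.

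Genes of sugar phosphotransferase systems, which import sugars with phosphate from phosphoenolpyruvate, moved mostly down. Of 65 tested members 11 fell and 3 rose, and adjusted over the list alone 13 fell and 4 rose. The median log2 fold change was -0.16 (camera, adjusted p = 0.00245, and adjusted p = 0.49 with an estimated correlation). The beta-glucoside transporter gene lp_3513 fell from 139.4 ± 9.50 to 74.2 ± 7.16 CPM (-0.91 ± 0.09, adjusted p = 0.000243 in edgeR). The N-acetylglucosamine EIIC gene lp_2649 fell by 0.65 on the log2 scale. The raffinose and melibiose transporter gene lp_3486, which fell by 0.73, matched by name as regulated by a phosphotransferase system and is itself of the GPH family, not such a system. These 3 genes passed in all 6 fits that left out 1 library.

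Genes in the list of cysteine and methionine metabolism were higher in treated cells. Of 16 members 4 rose and 0 fell, with the same counts adjusted over the list alone, and the median log2 fold change was 0.29 (camera, adjusted p = 0.00217, and adjusted p = 0.37 with an estimated correlation). Cystathionine beta-synthase, lp_0256, which joins serine and homocysteine, rose from 214.6 ± 16.6 to 320.3 ± 34.8 CPM (0.58 ± 0.09, adjusted p = 0.00354 in edgeR). Its neighbour lp_0255, a cystathionine lyase, rose by 0.46 and a further cystathionine beta-lyase gene, lp_2751, rose by 0.40 on the log2 scale. The fourth rise was of lp_3214, a cystathionine ABC transporter gene (0.57). The genes lp_2751 and lp_3214 lost their call without control replicate 3 and without treated replicate 1 or 3.

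Metal ion transport genes gave 4 rises and 0 falls among 26 tested, with the same counts adjusted over the list alone (median 0.12, camera adjusted p = 0.0161, and adjusted p = 0.49 with an estimated correlation). With genes under a mean of 50 counts left out, the adjusted p of this list was 0.0556. Besides lp_2992, the substrate-binding gene lp_3302 of a metal ion ABC transporter rose from 42.7 ± 3.43 to 62.5 ± 3.14 CPM (0.55 ± 0.11, adjusted p = 0.00805 in edgeR), and the gene of a cadmium, zinc and cobalt ATPase, lp_3327, rose by 0.48. Amino acid transport and peptidase genes gave 9 rises and 3 falls among 44, again with the same counts adjusted over the list alone (median 0.10, camera adjusted p = 0.0487, and adjusted p = 0.63 with an estimated correlation). The amino acid transporter gene lp_1120 rose by 0.58 and the branched-chain amino acid permease gene lp_0861 by 0.44 on the log2 scale, whereas another transporter gene, lp_2799, fell from 190.9 ± 1.46 to 128.9 ± 6.45 CPM. The call of this list was lost without control replicate 2 (adjusted p = 0.0641), control replicate 3 (0.171), treated replicate 1 (0.0826) or treated replicate 3 (0.0682), and with the length correction (0.18), limma-voom (0.0715) or the 50-count filter (0.0625). Its median was 0.05 without control replicate 3 or treated replicate 1. The gene lp_3327 lost its call without control replicate 3 or treated replicate 1.

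Ribosomal protein genes shifted slightly upwards, with 42 of 58 fold changes positive, 3 rises and 1 fall. Adjusted over the list alone, 2 rose and 0 fell. The median log2 fold change was 0.08 (camera, adjusted p = 0.0369, and adjusted p = 0.63 with an estimated correlation). The genes of S19 (lp_1038) and L16 (lp_1041) rose by 0.28 and 0.30 on the log2 scale. The member that fell, lp_0737, is annotated as ribosomal protein S30EA, a name used for a hibernation factor that binds ribosomes at low growth rates, and it went from 5922.4 ± 387.7 to 4943.7 ± 163.1 CPM (-0.26 ± 0.07, adjusted p = 0.0359 in edgeR). The list was no longer called without control replicate 3 (median 0.03, adjusted p = 0.177), without treated replicate 2 (adjusted p = 0.256) or with the 50-count filter (adjusted p = 0.0556), and without control replicate 2 its median was 0.13. The calls of lp_1038, lp_1041 and lp_0737 were lost without control replicate 3 or treated replicate 1, those of lp_1041 and lp_0737 also without treated replicate 3, and that of lp_0737 also without control replicate 1 or treated replicate 2. The fall of lp_0737 depended on scaling too, its call being lost with upper-quartile scaling and with library totals alone.

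**Figure D2:**
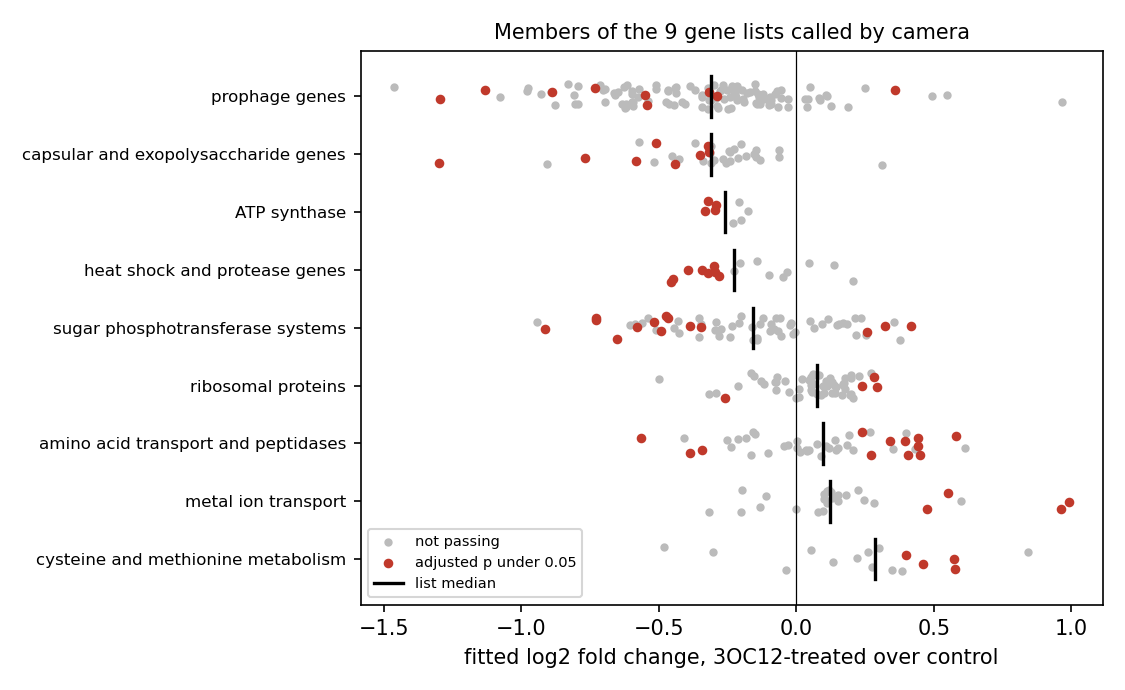
The plot of fold changes in the 9 gene lists called by camera. Each point is a tested gene at its fitted log2 fold change (treated over control), red points passed at an adjusted p under 0.05, and black bars are list medians, which run from -0.31 for the prophage genes to 0.29 for cysteine and methionine metabolism.

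Several groups related to the cell envelope and to resistance did not pass as lists. Multidrug efflux transporters had 3 rises and 0 falls among 24, with the same counts adjusted over the list alone (median 0.12, camera adjusted p = 0.0712). They passed without treated replicate 2 (median 0.17, adjusted p = 0.0412) and after thinning to the smallest library total (median 0.15, adjusted p = 0.0339). With the 50-count filter they passed too, at a median of 0.25 (adjusted p = 0.00766). The ABC transporter genes lp_3042 and lp_3040 rose by 0.41 and 0.42 on the log2 scale, from 128.0 ± 1.12 to 170.7 ± 10.9 CPM and from 131.2 ± 12.5 to 175.3 ± 12.4 CPM, and the EmrB family gene lp_3303 rose by 0.29. Cell surface anchored proteins gave 7 rises and 2 falls among 58, or 8 and 2 adjusted over the list alone (median 0.02, adjusted p = 0.309). They passed with treated replicate 2 as the lone treated library (adjusted p = 0.0437), and their median was -0.02 without treated replicate 2, 0.01 without treated replicate 1 and 0.04 without control replicate 3 or treated replicate 3. The mucus-binding protein gene lp_3059 rose from 279.0 ± 9.27 to 365.9 ± 9.37 CPM (0.39 ± 0.07, adjusted p = 0.00472 in edgeR), and lp_3412, of the CscB family, rose by 0.37. Peptidoglycan synthesis had 1 rise (lp_0518, 0.28) and 1 fall (lp_1233, -0.39) among 10, the latter a priming undecaprenyl-phosphate glucosephosphotransferase that matched by name and is no step of peptidoglycan synthesis, or 1 and 2 adjusted over the list alone, with a median of 0.01, a mean of -0.01 and an adjusted p of 0.957. Its median was -0.03 without treated replicate 1 and 0.03 without control replicate 2. Teichoic acid and D-alanylation genes gave 0 rises and 0 falls among 11 (median 0.06, adjusted p = 0.642), and membrane lipid genes 0 and 0 among 4 (median 0.13, adjusted p = 0.424), with 0 of each also adjusted over the list alone. The membrane lipid median was 0.06 without treated replicate 1 and 0.08 without control replicate 3, and the teichoic acid median 0.04 without control replicate 1. Of the changed genes named here, lp_3042 and lp_3059 passed in all 6 fits that left out 1 library. The other 5 lost their call without control replicate 3, as did lp_3040, lp_0518, lp_3303 and lp_1233 without treated replicate 1, lp_3303 and lp_1233 without treated replicate 3, and lp_1233 without control replicate 1 and after thinning.

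Fatty acid synthesis genes gave 5 rises and 1 fall among 20, also adjusted over the list alone, with a median of -0.04, a mean of 0.04 and an upward camera direction (adjusted p = 0.407). Its median was 0.04 without control replicate 2, -0.06 without control replicate 1 or treated replicate 2, -0.02 without control replicate 3 or treated replicate 3 and -0.01 without treated replicate 1. All 5 rises were in neighbouring genes, lp_0588 to lp_0592, which lie in the longest run described below and may not be separate responses. The rises named by rule were in acetyl-CoA carboxylase, which commits acetyl-CoA to fatty acids. They were lp_0590 (from 348.8 ± 22.5 to 443.7 ± 28.6 CPM, 0.35 ± 0.08, adjusted p = 0.0135 in edgeR), lp_0589 (0.36) and lp_0591 (0.36), and all 3 lost their call without control replicate 3 or treated replicate 1 and lp_0591 also without control replicate 2. Thiol and oxidative stress genes gave 2 rises and 3 falls among 28, or 3 and 3 adjusted over the list alone (median -0.02, adjusted p = 0.957, upward with the replicate block). Their median was 0.01 without treated replicate 1, -0.01 without control replicate 2 and -0.005 without any 1 of the other 4 libraries. Thiol peroxidase, lp_2323, fell from 395.8 ± 11.9 to 269.5 ± 18.7 CPM (-0.55 ± 0.07, adjusted p = 0.00127), and glutathione reductase, lp_3267, rose by 0.33 and NADH oxidase, lp_1925, by 0.30. The plantaricin list held 17 tested genes of the locus, which encodes bacteriocins and their peptide-based quorum sensing, and 6 from elsewhere that matched by product name. Of the 17, 0 passed. The fall among the 23 was of lp_0972 (-0.49), a bacteriocin immunity gene outside the locus, and adjusted over the list alone 0 fell (median -0.18, adjusted p = 0.109). The list passed without treated replicate 2 (median -0.39, adjusted p = 0.0376) and after thinning to the smallest library total (adjusted p = 0.0394). These were 2 of 18 refits. Without any other single library the list did not pass, with medians from -0.205 to -0.132. In the locus, the response regulator gene plnD, lp_0418, had a log2 fold change of -0.31 with an adjusted p of 0.0917, or 0.0344 with the replicate block. The calls of lp_3267, lp_1925 and lp_0972 were lost without control replicate 1 or 3 and without treated replicate 1 or 3. That of lp_0972 was also lost with DESeq2, limma-voom, upper-quartile scaling, library totals alone and both length corrections (called in 8 of 19 alternatives), and that of lp_1925 with DESeq2 and after thinning.

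No list of central metabolism or nucleotide synthesis was called. These lists can lack genes that were given by symbol alone. The glycolysis list was matched on the names of lactate dehydrogenases, phosphoglycerate kinase and phosphopyruvate hydratase. Other glycolytic enzymes, such as 6-phosphofructokinase (lp_1898), were not in it. Pyruvate dissipation genes gave 0 rises and 1 fall among 17, also adjusted over the list alone (median -0.05, camera adjusted p = 0.3), the fall being lp_2151, the E3 component of pyruvate dehydrogenase (-0.37, lost without control replicate 1 or 2 or treated replicate 3). Its partner lp_2152, the E2 component, was at -0.25 with an adjusted p of 0.0865, or 0.0358 with the replicate block. Glycolysis and lactate formation gave 0 rises and 0 falls among 7 (median 0.10, adjusted p = 0.531), and the lactate dehydrogenase gene lp_0537 was at 0.16 with an adjusted p of 0.308. Purine synthesis gave 0 and 0 among 12 (median 0.05, adjusted p = 0.459), with 0 and 0 for both lists also adjusted over the list alone. Pyrimidine synthesis gave 0 rises and 1 fall among 13, or 1 and 1 adjusted over the list alone (median 0.11, adjusted p = 0.424), the fall being lp_2704, a pyrimidine operon regulator (-0.37, lost without each of the control replicates, without treated replicate 1 or 2, with upper-quartile scaling and with library totals alone). Aromatic and histidine synthesis gave 0 and 0 among 18 by either adjustment (median -0.03, adjusted p = 0.957). SOS and DNA repair genes gave 1 rise and 0 falls among 6, or 2 and 0 adjusted over the list alone (median 0.12, adjusted p = 0.262), the rise being lp_2915, excinuclease subunit A (0.27, lost without control replicate 1 or 3 or treated replicate 1 or 3 and after thinning). Competence genes gave 0 and 0 among 6 by either adjustment (median 0.05, adjusted p = 0.957, downward by fry), with the competence repressor gene lp_2227 at -0.24 and an adjusted p of 0.0659, or 0.0257 with the replicate block. The medians of these lists depended on single libraries. Without control replicate 3 they were 0.01 (pyrimidine), 0.03 (glycolysis), 0.08 (SOS), -0.13 (pyruvate) and 0.02 (competence), and without treated replicate 1 they were 0.03 (pyrimidine), 0.05 (glycolysis) and -0.09 (aromatic). Without control replicate 1 they were 0.06 (glycolysis), 0.02 (purine) and 0.09 (competence), without control replicate 2 -0.03 (pyruvate), without treated replicate 2 0.01 (aromatic), and without treated replicate 3 0.04 (glycolysis), -0.10 (pyruvate) and -0.13 (aromatic).

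The neighbourhood of lp_0775 was chosen before the data were examined, from a recollection, which could not be checked here, that its promoter had been followed up after 3OC12. Its result is thus not an unselected one, and it is described whatever it was. This gene encodes argininosuccinate synthase, which joins citrulline and aspartate in arginine synthesis, and it rose from 85.2 ± 6.28 to 107.3 ± 4.95 CPM (0.33 ± 0.09, adjusted p = 0.0334 in edgeR). The next gene, lp_0776, argininosuccinate lyase, rose from 108.2 ± 4.61 to 145.6 ± 7.21 CPM (0.43 ± 0.08, adjusted p = 0.00727). Both are among the 4 members of the arginine list, which held 2 rises and 0 falls, also adjusted over the list alone, and was not called (median 0.19, camera adjusted p = 0.134), with a median of 0.11 without control replicate 1. On the other side, luxS, lp_0774, which makes the autoinducer-2 precursor, was at -0.04 ± 0.06 with an adjusted p of 0.714, and the excinuclease gene lp_0773 at 0.10 with an adjusted p of 0.361. The membrane protein gene lp_0778 was at -0.26 with an adjusted p of 0.0843, or 0.0153 with the replicate block. The 3 candidate lactone hydrolases, lp_2122 and lp_2158 of the metallo-beta-lactamase superfamily and the 6-phosphogluconolactonase lp_2219, held 0 rises and 0 falls by either adjustment (median 0.02, adjusted p = 0.957), with medians from -0.06 without treated replicate 1 to 0.08 without treated replicate 2. The call of lp_0775 was lost without control replicate 1 or 3 and without treated replicate 1 or 3.

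Changed genes were neighbours more often than by chance, as genes of an operon would be. There were 18 runs of at least 3 neighbouring tested genes that all passed in the same direction, 9 up and 9 down with 64 genes in all, against a mean of 1.3 and a highest value of 7 over 10000 shuffles of the calls (permutation p = 1e-04, the smallest they can give). The longest was a run of 7 genes that rose, from lp_0587 to lp_0593, at chromosome positions 561614 to 567831. It starts with the EIIB gene of a mannose phosphotransferase system (lp_0587, 0.26 on the log2 scale, adjusted p = 0.0492 in edgeR), holds 4 genes of acetyl-CoA carboxylase subunits, of which lp_0592 had the largest change (0.40), and ends with a LytR family gene, lp_0593 (0.37 ± 0.07, adjusted p = 0.00782 in edgeR). The call of lp_0587 held in 7 of 19 alternatives and was lost with DESeq2, limma-voom, RLE scaling, the 50-count filter, RNA genes left out and thinning, so the run does not start there in those fits. A run of 6 that fell, lp_2647 to lp_2652 at 2354927 to 2359363, holds an N-acetylglucosamine phosphotransferase system and ends with a UspA family gene. Its members fell by 0.42 to 0.65 on the log2 scale. The 3 runs of 4 genes were lp_2002 to lp_2005 (1808474 to 1811391, down, with the membrane protein gene lp_2004 at -0.58), lp_2368 to lp_2371 (2139188 to 2142278, down, ATP synthase subunits and the uracil transporter gene lp_2371 at -0.50) and lp_3209 to lp_3214 (2860144 to 2863783, up, cystine and cystathionine ABC transporters, with lp_3214 at 0.57). With the replicate block there were 33 runs, and there were 10 without control replicate 1, 4 without control replicate 3, 5 without treated replicate 1 and 9 without treated replicate 3. Of the 13 genes named by the rule for runs, 6 passed in all 6 fits that left out 1 library, with 6 calls lost without control replicate 3, 6 without treated replicate 1, 4 without treated replicate 3, 3 without control replicate 2, and 1 each without control replicate 1 and treated replicate 2.

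The RNA composition was compared as a check of the libraries. The 3 small stable RNAs (RNase P RNA, tmRNA and 4.5S RNA) took 3.95% ± 0.58 of counts in control and 3.04% ± 1.05 in treated libraries (SD, n = 3, exact two-sided permutation p = 0.3, where 0.1 is the smallest possible). The share was 2.47% and 2.40% in treated libraries 1 and 3, but 4.25% in treated library 2. Within the same-numbered pairs the share went down in 3 of 3, from 4.19% to 2.47%, 4.37% to 4.25% and 3.28% to 2.40% (exact sign-flip permutation p = 0.25, the smallest that 3 pairs can give), as did that of RNase P RNA. That of tmRNA went down in 2 of 3, and that of 4.5S RNA went up in 3 of 3, from 0.00199% ± 0.000121 to 0.00265% ± 0.000206 (exact p = 0.1). The difference of means was -1.51 percentage points without treated replicate 2 and -0.59 without treated replicate 3. Genes of the plasmid pWCFS103 took 0.459% ± 0.020 and 0.503% ± 0.018 (exact p = 0.1), tRNA genes 0.0238% ± 0.0006 and 0.0228% ± 0.0048 (exact p = 0.9), and rRNA genes 0.00101% ± 0.00026 and 0.00469% ± 0.00656 (exact p = 0.7). The rRNA share was 0.0123% in treated library 1 (317 counts) but 0.00108% and 0.000715% in treated libraries 2 and 3. Treated library 1 also stood apart in reads of low alignment quality (1.16% of its reads), and its deposited summary total was the only one that matched the sum over all genes. The lowest correlation between any 2 libraries was a Pearson r of 0.986 over log2 CPM, across genes that are not independent replicates. The first principal component, with 40.4% of the variance, separated all 3 treated from all 3 control libraries. A second component, with 22%, set replicate 2 of both groups (-5.78 in control, -9.53 in treated) apart from the other libraries (2.02 to 5.34). RNase P RNA was also highest in replicate 2 of each group (2.15% in control, 1.43% in treated). Part of the spread thus followed the replicate number in both groups. Shorter genes were lower in treated libraries, with a median log2 fold change of -0.13 for the 270 genes up to 300 nt and 0.05 for the 162 longest genes.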

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

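All tests in this part were chosen after the result was seen, apart from the planned fits that left out 1 library and the planned list tests, fry and camera with an estimated correlation. Reads that the comparison did not use showed a signal over 1.5 times that of every control library. Reads of low alignment quality made up 1.156% of the reads of treated library 1 (95% Wilson interval 1.144 to 1.168, counting error only), against 0.264%, 0.368% and 0.285% in the controls and 0.266% and 0.264% in the other treated libraries.

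Shorter genes were lower in treated libraries, with a Spearman rho of 0.161 between length and log2 fold change across genes, which are not independent. After all libraries were thinned to the smallest total, rho was 0.162. Thinning keeps the expected share of each gene, so this value argues at most against unequal counting noise. It cannot address a bias that arose while the shallow libraries were made. The deviations of single libraries gave a rho with length of 0.192 and 0.137 in treated libraries 1 and 3, but -0.062 in treated library 2, inside the control range of -0.235 to 0.014. Control library 2 gave 0.014, and control libraries 1 and 3 gave -0.157 and -0.235. Replicate 2 of each group thus lay between the other controls and the other treated libraries. A loss of short transcripts in treated libraries 1 and 3 would give their higher values, though not the spread among the controls. The summed share of small stable RNA was lowest in treated libraries 1 and 3. But 4.5S RNA, the weakest of the 3, had its highest shares there (0.00275% and 0.00278%), from 71 and 70 counts. The 95% Wilson intervals of these shares overlap those of every other library. In treated library 1 the interval was 0.00218 to 0.00346, and in treated library 2 it was 0.00200 to 0.00291. The 4.5S shares thus weigh little, and loss of short transcripts stays open as an explanation. An effect of 3OC12 that was weaker in treated library 2 stays open and was not tested.

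Prophage genes had a median log2 fold change of -0.312, and after length correction it was -0.269 (camera adjusted p = 0.000212), which argues against length as the whole cause. Among 10000 random lists matched on mean expression the median lay at percentile 0.01, the smallest they can give, so a shift of all weakly expressed genes is argued against too. The list was called in 6 of 6 fits that left out 1 library, although its median was -0.205 without treated library 2. With an estimated correlation the adjusted p was 0.638, and fry gave 0.289, so neither called the list. A response to 3OC12 is a hypothesis only, and reads shared between near-identical prophage copies stay open.

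Polysaccharide genes had a median of -0.310, which was -0.316 after length correction (adjusted p = 4.38e-07). The median lay at percentile 0.01 of lists matched on mean expression, and the call held in 6 of 6 fits that left out 1 library. Length, weak expression and a lone library are thus each argued against as the whole cause, and a response to 3OC12 is a hypothesis found and tested on the same data. With an estimated correlation the adjusted p was 0.487 and fry gave 0.0721, so neither called the list, which leaves open whether neighbouring genes under a shared control count as many.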

How the results depend on the processing

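No named gene or list reversed its direction where it was called. DESeq2 called 325 genes (152 up, 173 down) among 2029 with an adjusted p, and over all alternatives that kept every library the count of changed genes lay between 320 and 540. The lists of polysaccharide, prophage, ATP synthase, heat shock, phosphotransferase and cysteine and methionine genes were called by camera at the preset correlation in all 18 refits. An estimated correlation called 0 lists and fry 4. With the replicate block, 540 genes (242 up, 298 down) and 33 runs were called, 8 further named genes passed, and no other call changed. With block and length correction there were 32 runs. Genes changed at least 2-fold numbered 4 with DESeq2 and 4 with the 50-count filter, which tests fewer weakly expressed genes. Runs numbered 64 at a minimum of 2 genes and 5 at 4 (permutation p = 0.001 each, the smallest that 1000 shuffles can give). With treated library 2 alone against the controls, assumed to vary as they do, 50 genes and 4 runs were called, and 58 named genes lost their call. Leaving out 1 library gave 120 to 434 changed genes, 6 to 23 changed at least 2-fold, 7 to 11 lists and 4 to 17 runs, and a share difference of small stable RNA of -1.51 to -0.59 percentage points, with fewer samples in each case. Of 76 named genes that passed, 37 passed in all 6 of these fits, and 37 lost their call without control replicate 3. Alternatives for normalized values and for strand were not run, since the table holds counts and no strand. The cause of the other differences was not tested. The self-test recovered 66% at 1.3-fold among genes above a minimum mean count, so what depth hides in genes with few counts was not measured.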

Other observations

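All tests in this part were chosen after the results were seen, apart from the other splits of the libraries. Aminoacyl-tRNA synthetases, which load tRNAs with amino acids, were higher in treated cells, with 8 rises and 0 falls among 23 tested genes and a median log2 fold change of 0.19. The rises were in the genes of the tryptophan (lp_0434, 0.46), glycine (lp_1964, 0.36), phenylalanine (lp_1558, 0.34, and lp_1559, 0.33), glutamate (lp_0609, 0.32), histidine (lp_1981, 0.26), serine (lp_1012, 0.24) and arginine (lp_1391, 0.22) enzymes. Camera gave p = 2.95e-07 and p = 8.16e-06 after length correction, but p = 0.0608 with an estimated correlation. The group was picked because its members stood out, so the p-values are not independent evidence.

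A group matched by product name to sugar and polyol enzymes and transporters, sugar phosphotransferase system genes excluded, was lower, with 15 falls and 0 rises among 66 tested genes and a median of -0.10 (camera p = 0.000114, p = 5.26e-06 after length correction, and p = 0.0456 with an estimated correlation). Besides galactokinase, they included maltose phosphorylase (lp_1730, -0.68), xylulose-5-phosphate phosphoketolase (lp_3551, -0.66), alpha-mannosidase (lp_3631, -0.61), aldose 1-epimerase (lp_1731, -0.61), a 6-phospho-beta-glucosidase (lp_3512, -0.55) and mannitol-1-phosphate dehydrogenase (lp_0233, -0.38). The match was loose. Of the 15 falls 3 were in dihydroxyacetone phosphotransferase and transport genes (lp_0169, lp_0170 and lp_0171), and the 66 also held 3 diacylglycerol kinase genes, of which 0 fell, and 1-deoxy-D-xylulose-5-phosphate synthase (lp_2610). The group was also chosen from the values and was narrowed once after a first version of it had been seen, so its p-values are not independent evidence.

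Fold changes differed between stretches of the chromosome. Medians over 200 kb ran from -0.17 at 2000001 to 2200000 and -0.16 at 3200001 to 3400000 up to 0.12 at 1600001 to 1800000 and 0.11 at 400001 to 600000. Their SD was 0.094, against a mean of 0.042 and a highest value of 0.076 over 10000 shuffles of blocks of 10 genes (permutation p = 1e-04, the smallest they can give), and p = 0.0027 with blocks of 50 genes. Without the prophage and polysaccharide genes the SD was 0.091, so those clusters do not account for it. Other splits of the 6 libraries gave at most 0.046, but they mix treated and control libraries, so lower values are likely in any case. Distance from the replication origin, taken as position 1, showed a Spearman rho of 0.009 over 2883 genes, which argues against a gradient of gene dosage. What sets the stretches apart was not tested.

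Other splits of the 6 libraries into 3 and 3 number 10 with the real split, too few for a share under 0.05. In each of the following counts 1 of the 10 splits, the real one, gave as large a value. The real split called 362 genes and the highest other 1, 9 against 1 at 2-fold or more, 9 against 6 lists, and 18 against 0 runs. All other splits mix treated and control libraries in both groups. This dilutes any difference between the real groups and adds it to the spread within the mixed ones. Few gene and run calls are thus likely there whatever made the real groups differ, and these counts are no evidence for a cause. Every other split called 2 to 6 lists by camera at the preset correlation, while calling 0 or 1 gene. These mixed groups still hold unequal numbers of treated libraries, so part of a treatment difference remains in them. Which lists they called was not compared with the real split. The splits thus cannot tell how often lists are called at the preset without a treatment effect. A list call at the preset stays weak evidence, since with an estimated correlation 0 lists were called. The other 3 splits that part every same-numbered pair called 0, 1 and 0 genes and 3, 2 and 5 lists.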
